A study of Arabidopsis thaliana and Homo sapiens with 42 samples.

How the data were processed

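RNA-seq was collected from a human cell line and from Arabidopsis thaliana. HEK293T RMCE is a line derived from human embryonic kidney cells that carries a landing site for recombinase-mediated cassette exchange, by which constructs can be inserted at a fixed locus. Per the labels, these cells were transfected with Flag-tagged LUC7L, LUC7L2 or LUC7L3 or with a control, which the library names call eGFP, and RNA was taken 1 day later. Seedlings of the wild type Col0 and of 9 luc7 mutant genotypes were grown on plates in continuous light. All libraries were stranded, made from poly(A) RNA and read as pairs. The labels gave 42 samples in 14 groups of 3. Nothing in the labels says that the replicates of a group came from separate cultures or plant pools. The p-values of single exons thus measure the spread between these samples, which may be technical. Tests of splice sites, directions and gene lists count exons or genes as units, which are not independent. Their p-values hold no spread between libraries.

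Each of the 12 deposited tables compared 1 overexpression or 1 mutant group with its control and listed skipped-exon events, in which an exon is joined to both neighbours or left out. Per the file headers, each event had its gene, the exon and its 2 flanking exons, and the inclusion and skipping junction reads of each library. The layout, per the file headers, was that of the skipped-exon output of rMATS, with 5 columns added. The aligner, the splicing tool and its version, the annotation and the correction behind the added columns were not given in the sources used here. The builds, hg38 and TAIR10, came from the submitters' processing notes. The authors deposited p-values and FDR values per event, group PSI values as fractions after a correction that no header describes, and differences of these fractions as signed scores from -1 to 1. Here they were used only for comparison. The corrected FDR was set aside, because for the triple mutant it was under 0.05 in 5967 of 6681 events, 3212 of them with the authors' own deposited p-value at 1. In the other 11 tables no event with a p-value of 1 did so.

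The tables name their sides only as sample 1 and sample 2. The second side was taken as the control, because its reads were identical in every shared event of all tables of an organism, and the first side was named from the match between the table's name and the library names. The 3 reads in a cell carry no replicate number. Replicate numbers below are therefore positions in a cell, and no library was paired with another.

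Percent spliced in (PSI) was computed for each library as the length-normalised share of inclusion reads. The event with the most reads stood for each exon. An exon was tested if every library of the comparison had at least 10 reads and each form had at least 10 reads over all libraries. Odds ratios used a floor below a whole read where a group had no read of a form. The test planned before the data were examined was the quasi-likelihood test of a count package. The cells joined the counts of 3 libraries by commas, and a quasi-binomial model of inclusion against skipping reads with the same structure replaced it. The cells were split into counts per library for this model, and the planned test was not run on them. Dispersions were moderated towards a trend on mean reads by the empirical Bayes step of limma 3.58.1 in R 4.3.3 and held at 1 or above, and groups were compared by a 2-sided F test. The replacement was settled after the file format and the tallies of the authors' FDR had been seen, and before any result of the tests run here. Benjamini-Hochberg adjustment gave the moderated FDR. An exon was called at FDR under 0.05 with a difference of mean PSI of at least 10 points. Values are mean ± SD of 3 libraries per group unless stated otherwise.

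The model was tested on simulated data built from each comparison's own libraries. Changes were placed only in exons of middling inclusion, so recovery at exons near full inclusion or full skipping was not measured. Of exons changed by 10 points, 3.33% (luc7a-2 luc7b-1) to 13.4% (LUC7L2) were found, of those changed by 20 points 13.8% (luc7a-1 luc7b-1) to 44.8% (LUC7L2), and of those changed by 30 points 48% (luc7a-2) to 75.9% (luc7a-1 luc7b-1). The false share among simulated exons under the FDR threshold was 7.04% for LUC7L, 7.32% for LUC7L2, 14.8% for LUC7L3, 10.3% for luc7a-1, 11.5% for luc7a-2, 9.68% for luc7b-1, 14.3% for luc7rl-1, 3.45% for luc7a-1 luc7b-1, 13.3% for luc7a-1 luc7rl-1, 14.7% for luc7a-2 luc7b-1, 4.55% for luc7b-1 luc7rl-1 and 4.76% for the triple mutant. In the direct tests it was 11.1% for LUC7L3 against LUC7L2, 10.8% for LUC7L3 against LUC7L, 7.14% for LUC7L2 against LUC7L, 5.88% for the triple mutant against luc7a-2 luc7b-1, 6.67% for luc7a-2 against luc7a-1, 12.1% for luc7a-2 luc7b-1 against luc7a-1 luc7b-1 and 3.85% for luc7rl-1 against luc7a-2 luc7b-1. The share thus lay above the nominal 5% in all but 4 of the 19 comparisons, and the model was not tuned afterwards. Each share came from 1 simulated set and rested on few false calls, from 1 in luc7a-1 luc7b-1 to 13 in LUC7L3. It does not show in which single comparisons the FDR exceeds 5%. An exon not called is not shown to be unchanged. Before averaging, replicates were compared. The mean chi-square per exon between libraries of a group, 1 if only counting differed, ran from 2.28 to 3.19 in human cells and from 3.99 to 7.99 in seedlings. No pair looked like 1 library deposited more than once.

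Splice sites were read on the strand of the gene. In Arabidopsis all 18483 sites came from the TAIR10.1 genome, and 99.995% were annotated exon ends. No human genome sequence was used here. Human bases came from GENCODE v29 transcripts, which gave the last 3 exon bases for 98.6% of 135071 sites but intron bases for only 20.0%, where another transcript runs through the site. The planned human score over both sides of the site was void for this reason, being under the 80% needed, and an exon-side score was added after the data were seen. Scores are log2 odds of each base among the sites of all exons tested in the organism against equal base frequencies, over the last 3 exon bases and intron positions +3 to +6, at sites whose intron starts with GT. Overlapping exons with the same 5' splice site were counted separately. The balance is the intron-side minus the exon-side score, so positive values mark sites with their strength on the intron side. Score differences were tested by 2-sided permutation, with 100000 draws or exactly where a group had under 10 exons and all regroupings were few enough to list, and shares by Fisher's exact test with Benjamini-Hochberg adjustment over 15 shares compared. The 6 shares compared at upstream exons in seedlings were added after the data were seen and adjusted among themselves. Intervals of shares are exact Clopper-Pearson intervals at 95%.

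Gene lists were fixed before the data were examined. The human lists were U1 snRNP and U1-associated proteins, the rest of the spliceosome, SR proteins, hnRNP and related regulators, nonsense-mediated decay, cleavage and polyadenylation, cell cycle and mitosis, DNA damage response, centrosome and cilium, chromatin and transcription regulators, glycolysis, the mitochondrial respiratory chain, genes with neuronal microexons and genes with epithelial ESRP-type exons. The plant lists were U1 proteins, SR proteins, glycine-rich, PTB and UBP1 RNA-binding proteins, nonsense-mediated decay, circadian clock, flowering time, light signalling, abscisic acid and abiotic stress, leaf photosynthesis genes and root-expressed genes. The share of tested genes with a called exon was compared with that of all other tested genes by Fisher's exact test, adjusted over the lists. Genes with more testable exons have more chances of a call, which this test does not correct. Named exons followed a rule fixed beforehand. It took the 10 largest rises and falls, 1 exon per gene, where the 3 libraries of one group all lay above those of the other, for each overexpression and the triple mutant. It took 3 each way for the other mutants, 5 each way for direct tests of overexpressed proteins and of the triple against a double mutant, up to 4 called genes per list, and every tested exon of a LUC7 gene. Exons behind counts of 5 or fewer, exons called in opposite directions, and list members in direct tests were chosen after their values were seen.

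Comparisons that share controls share chance values. For each pair, 20 sets of unchanged groups and of the controls they share were simulated at the real read depths. Inclusion was pooled over both groups and the controls, and the larger of the fitted dispersions was used. The real controls' own inclusion values thus did not enter, and the larger dispersion can raise the simulated covariance. The alternatives tried were other size thresholds, read minimums and event choices, limma on logit PSI, the authors' FDR, and leaving out each library. Thinning to equal total reads over the events listed in every table of an organism (reads per exon were not equalised), centring on a median odds ratio, a variant of the read filter, the exon-side score and the comparison of lowered with other exons were added after the data were seen. Other tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.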

Results

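LUC7 proteins belong to the U1 snRNP, the particle that recognises the 5' splice site, and the series asks whether members of the family act on different classes of these sites. Exon skipping was measured from junction reads in HEK293T RMCE cells overexpressing LUC7L, LUC7L2 or LUC7L3 and in Arabidopsis seedlings carrying mutations in LUC7A, LUC7B and LUC7RL. There were 3 libraries of each of the 4 groups of human cells and of the 10 plant genotypes. The control cells had 42.4, 25.9 and 34.2 M (mega) junction reads over the events of the LUC7L table, against 69.7, 34.2 and 67.1 M in the LUC7L libraries. In their own tables, counted in the same way, LUC7L2 libraries had 31.8, 60.8 and 61.7 M, and LUC7L3 libraries 65.2, 24.1 and 64.8 M. Over the events listed for their own comparison, plant libraries ranged from 2.86 M in the second luc7a-2 library to 8.25 M in the third library of the triple mutant. Over all 3063 events listed in every plant comparison, a different measure, they ranged from 2.29 M in the first luc7a-1 luc7rl-1 library to 4.92 M in the third luc7a-1 luc7b-1 library. A table listed between 136469 and 147917 events in human cells and between 4283 and 6681 in seedlings.

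Each transfected gene drew more junction reads in its own libraries than in control cells. LUC7L drew 99990 ± 14353 RPM (reads of the gene's listed junctions as a share of all listed junction reads; SD, n = 3) against 219 ± 19.6 in control cells. LUC7L2 drew 38456 ± 7927 RPM against 461 ± 14.3, and LUC7L3 4935 ± 532 against 192 ± 11.8. A read counts once for each listed event it belongs to, and the genes had 21, 17 and 16 listed events. These values thus do not measure amounts between genes, and protein was not measured. Equal amounts of the overexpressed proteins are not shown. Reads of the construct and of the endogenous gene were not told apart, so exons of the transfected gene are not read as endogenous splicing there. Of the mutants' LUC7 genes, LUC7A and LUC7RL had no listed event. In luc7b-1 the only listed event of LUC7B (AT5G17440) drew 72 ± 17.5 RPM against 69.3 ± 10.6 in Col0. In the other luc7b-1 lines it drew 44.6 ± 0.858 against 64.0 ± 10.6 (luc7a-1 luc7b-1), 64.5 ± 10.7 against 58.8 ± 8.98 (luc7a-2 luc7b-1), 47.6 ± 3.52 against 63.6 ± 10.0 (luc7b-1 luc7rl-1) and 36.9 ± 1.33 against 48.6 ± 7.77 (triple mutant), so it went both ways. It concerns the exon at chromosome 5, 5750713 to 5750776 of TAIR10, within the coding sequence. Reads there say nothing of whether the protein is made, so the mutants' labels were not checked by these values.

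After LUC7L overexpression, an exon of CDK10, a cyclin-dependent kinase, fell from 98.0% ± 3.51 to 32.1% ± 7.77 (SD, n = 3; FDR 2.58e-06; chromosome 16, 89694931 to 89695052 of hg38, within the coding sequence). The exon of CCNT2 (chromosome 2, 134953230 to 134953268, coding), a cyclin of the elongation factor P-TEFb, fell from 85.5% ± 19.8 to 24.1% ± 3.73 (FDR 5.37e-11). CEP97, whose product restrains cilium formation, had an exon of 99.3% ± 1.26 inclusion in control cells and 45.5% ± 13.1 after LUC7L (FDR 8.85e-10; chromosome 3, 101757811 to 101758423, coding). BCL9, a coactivator in Wnt signalling, went from 100% in all 3 control libraries to 44.9% ± 9.11 (FDR 0.000152). GBF1 fell from 70.7% ± 20.9 to 14.3% ± 4.43 (FDR 7.93e-05).

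Fewer exons rose after LUC7L. An exon of GNGT1 outside the annotated coding sequence (chromosome 7, 93886506 to 93886549), a gene for a transducin subunit, rose from 11.6% ± 5.68 to 63.0% ± 8.73 (FDR 0.000155). A coding exon of REXO5, an RNA exonuclease, rose from 45.5% ± 8.79 to 79.4% ± 3.42 (FDR 2.43e-05), and one of ATXN7, a subunit of the SAGA coactivator, from 20.7% ± 2.22 to 53.1% ± 4.09 (FDR 3.23e-07). PHC3, a Polycomb protein, rose from 10.4% ± 1.71 to 42.3% ± 5.65 (FDR 8.1e-06). Of 35696 exons tested, 2204 were called, 124 with higher and 2080 with lower inclusion. Thus 94.4% of calls were lower, and limma on logit PSI called 977. The median tested exon moved by -0.67 in log2 odds of inclusion. Centred on that median, 823 exons were higher and 846 lower, and relative to exons tested in every comparison, whose median moved by -0.48, 462 were higher and 1057 lower.

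Among the gene groups, chromatin and transcription regulators had called exons in 27 of 74 tested genes after LUC7L, all lower, against 16.5% of other genes (28 adjusted over the list alone; Fisher's exact test, adjusted p 0.000423). HDAC1, a histone deacetylase, fell from 94.9% ± 0.537 to 82.6% ± 3.74, and CREBBP, a histone acetyltransferase, from 95.7% ± 1.99 to 72.3% ± 7.20. DNA damage genes had calls in 21 of 59, 2 with higher and 19 with lower exons (22 adjusted over the list alone; exact adjusted p 0.00241). Among them the checkpoint kinase CHEK1 fell from 85.4% ± 1.25 to 66.3% ± 4.40 and the adaptor MDC1 from 97.4% ± 1.82 to 82.5% ± 3.44. Centrosome and cilium genes had calls in 22 of 67, all lower (20 adjusted over the list alone; exact adjusted p 0.00629), and genes known for epithelial ESRP-type exons in 9 of 22, all lower (9 adjusted over the list alone; exact adjusted p 0.0210). In that last list NUMB, a regulator of Notch signalling, fell from 95.2% ± 0.752 to 75.9% ± 0.376 and ARHGEF11 from 98.6% ± 1.35 to 73.4% ± 0.853. These directions did not hold relative to the median exon for DNA damage genes, with 10 genes higher and 9 lower, and ESRP-type genes, with 5 and 4. On the same scale 16 chromatin genes were lower against 7 higher, and 10 centrosome genes against 6. Relative to shared exons lower genes outnumbered higher ones in all 4 lists, by 10 to 6 in DNA damage, 4 to 1 in ESRP-type, 19 to 5 in chromatin and 13 to 4 in centrosome genes.

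Other lists did not differ detectably from the remaining genes after LUC7L. Cell cycle genes had calls in 12 of 58 (12 adjusted over the list alone; exact adjusted p 0.483). AURKB, a mitotic kinase, fell from 86.3% ± 3.50 to 56.6% ± 2.63, and PLK4, the kinase of centriole duplication, from 97.7% ± 2.62 to 62.0% ± 4.52. SR proteins, which bind exonic enhancers, had calls in 5 of 18 (5 adjusted over the list alone; exact adjusted p 0.358). An exon of SRSF6 fell from 30.4% ± 2.6 to 11.1% ± 0.424 (chromosome 20, 43459153 to 43459420, partly coding), and one of SREK1 from 97.6% ± 1.61 to 77.7% ± 3.19. The U1 list, which includes the transfected genes, had 4 of 18 (4 adjusted over the list alone; exact adjusted p 0.611). PRPF39, a U1 accessory protein, fell from 43.1% ± 2.77 to 16.4% ± 1.1 (chromosome 14, 45109894 to 45109993, outside the coding sequence). The rest of the spliceosome had 10 of 54 (11 alone), hnRNPs 10 of 46 (10 alone), cleavage and polyadenylation 5 of 20 (5 alone) and nonsense-mediated decay 6 of 18 (6 alone; exact adjusted p 0.214). Neuronal microexon genes had 6 of 32 (6 alone), the respiratory chain 5 of 69 (5 alone; exact adjusted p 0.0956) and glycolysis 1 of 25 (1 alone). In these, the cytochrome CYC1 fell from 97.8% ± 2.16 to 85.8% ± 3.62, and PDK1 rose from 68.0% ± 14.7 to 87.3% ± 1.83.

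LUC7L2 overexpression lowered USP10, a deubiquitinase, from 93.1% ± 3.29 to 44.5% ± 8.40 (SD, n = 3; FDR 5.96e-24; chromosome 16, 84745613 to 84745673, coding). ASNSD1 fell from 90.9% ± 3.11 to 46.9% ± 7.32 (FDR 2.47e-25; chromosome 2, 189666041 to 189666153, partly coding), and DSN1, a kinetochore protein, from 84.1% ± 5.51 to 41.2% ± 5.51 (FDR 1.32e-22). CCNT2 fell here too, to 37.2% ± 11.5 (FDR 9.28e-08). CDKN1A, the cell cycle inhibitor p21, rose from 8.65% ± 5.12 to 41.6% ± 13.3 at an exon outside the coding sequence (FDR 0.00368; chromosome 6, 36677902 to 36677933). DNM1, a dynamin, rose from 64.7% ± 2.56 to 90.8% ± 5.06 (FDR 0.000362), and REXO5 to 73.1% ± 3.99 (FDR 0.000944). SRSF6 fell to 12.7% ± 0.900 (FDR 2.98e-41), SREK1 to 77.8% ± 6.37, PRPF39 to 19.8% ± 1.18 (FDR 3.76e-12) and CEP97 to 62.8% ± 2.71 (FDR 7.88e-06). An exon of HNRNPH1 rose from 60.1% ± 0.434 to 70.2% ± 4.08 (FDR 4.96e-15).

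Of 32991 exons tested after LUC7L2, 882 were called, 70 higher and 812 lower (92.1% lower), and 6528 had an unadjusted p under 0.05. The limma fit on logit PSI called 0 at its own FDR threshold, and without the first control library the count was 583. Relative to the median exon, which moved by -0.36 in log2 odds, 249 were higher and 359 lower, and relative to shared exons, which moved by -0.28, 188 and 432. No list differed detectably from other genes. Centrosome and cilium genes came closest, with calls in 12 of 69 (12 adjusted over the list alone; exact adjusted p 0.0598), then chromatin regulators with 12 of 73 (14 adjusted over the list alone; exact adjusted p 0.0728) and SR proteins with 4 of 18 (4 adjusted over the list alone; exact adjusted p 0.184). Among chromatin regulators the methyltransferase SETDB1 fell from 95.5% ± 3.17 to 72.2% ± 2.49 and EP400 from 96.5% ± 0.736 to 72% ± 3.02.

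After LUC7L3 overexpression, ASNSD1 fell to 52.3% ± 6.31 (SD, n = 3; FDR 5.03e-21), CAP2, which binds actin, from 100% in all 3 control libraries to 68.1% ± 10.9 (FDR 4.46e-05; chromosome 6, 17507169 to 17507312, coding), and P4HA2, a collagen prolyl hydroxylase subunit, from 98.4% ± 2.73 to 63.7% ± 4.74 (FDR 0.00358). PARP2, which senses DNA breaks, fell from 95.5% ± 1.27 to 78.6% ± 4.04 (FDR 4.29e-09). The endogenous LUC7L gene, not transfected in these cells, had an exon that fell from 39.3% ± 1.3 to 15.7% ± 2.40 (FDR 2.29e-17; chromosome 16, 228333 to 228402, coding). SECISBP2, needed for selenoprotein synthesis, rose from 12.4% ± 1.46 to 35.2% ± 8.44 (FDR 0.000221; chromosome 9, 89334025 to 89334155, outside the coding sequence), and ZDHHC16, a palmitoyltransferase, from 29.2% ± 2.36 to 49.0% ± 2.08 (FDR 5.62e-05). DNM1 rose to 85.3% ± 3.31 (FDR 0.0234).

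Cell cycle genes had calls in 6 of 57 after LUC7L3, all lower (7 adjusted over the list alone; exact adjusted p 0.0413). Cyclin E1 (CCNE1) fell from 77.5% ± 5.15 to 58.2% ± 3.34, the phosphatase CDC25C from 94.5% ± 5.28 to 67.5% ± 9.83 and the kinase AURKA from 97.1% ± 1.45 to 86.8% ± 1.31. SR proteins had 3 of 18, all lower (3 adjusted over the list alone; exact adjusted p 0.0452). SRSF6 fell to 17.8% ± 0.438, SREK1 to 83.6% ± 7.42 and PNISR from 78.7% ± 3.77 to 62.3% ± 0.5. The U1 list also had 3 of 18 (4 adjusted over the list alone; exact adjusted p 0.0452). LUC7L fell and PRPF39 rose to 55.5% ± 5.14 (FDR 0.0149). Centred on the median exon, the counts were 2 lower cell cycle genes, 2 lower SR genes, and 1 higher and 1 lower U1 gene. Centred on shared exons, they were 4 lower, 3 lower, and 1 higher and 1 lower. Of 32883 exons tested, 264 were called, 30 higher and 234 lower (88.6% lower), and 4787 had an unadjusted p under 0.05, but the limma fit called 0. Centring on the median exon, which moved by -0.20, gave 73 higher and 108 lower, and on shared exons, which moved by -0.13, 53 and 144. Single libraries mattered here: the count was 131 without the first and 414 without the third LUC7L3 library, and 122 and 155 without the first and the third control library.

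**Figure D1:**
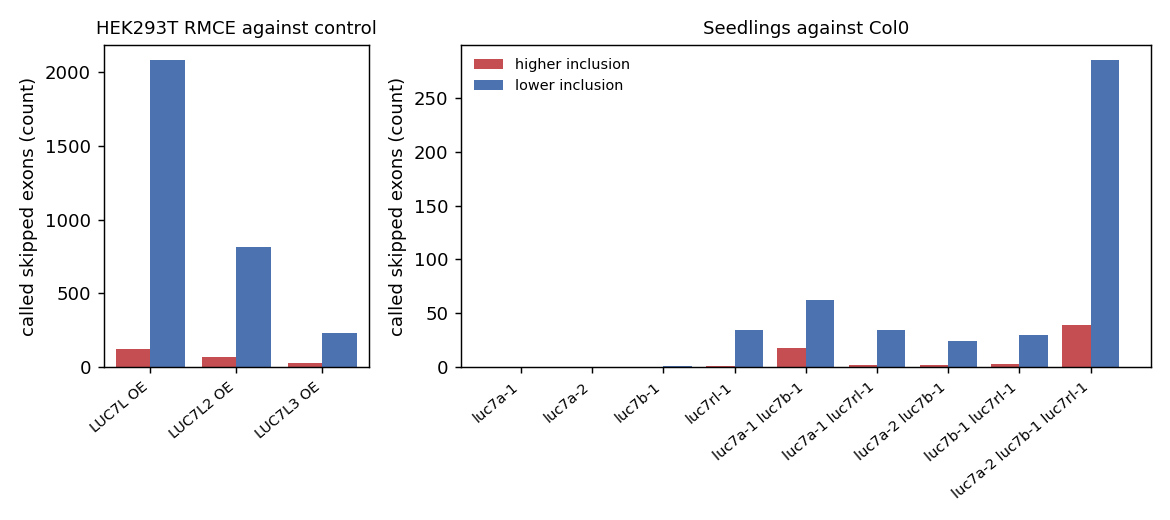
Bars give the number of exons called with higher (red) or lower (blue) inclusion than in the control group, for the overexpressed proteins and for the luc7 mutants in separate panels. Lower calls outnumbered higher ones in every comparison with 10 or more calls, from 2080 against 124 after LUC7L to 62 against 18 in luc7a-1 luc7b-1, but relative to the median exon the excess was reversed in every plant genotype with 10 or more calls, and relative to shared exons in none of them.

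Exons lowered by LUC7L2 and by LUC7L3 ended in different bases. After LUC7L2, 71.1% of lowered exons ended in AG (exact 95% interval 67.9 to 74.2, n = 810), after LUC7L 68.2% (66.2 to 70.2, n = 2075), but after LUC7L3 only 23.9% (18.6 to 29.9, n = 234). The higher exons went the other way, with 30% (19.6 to 42.1, n = 70), 36.3% (27.8 to 45.4, n = 124) and 93.1% (77.2 to 99.2, n = 29) ending in AG, against 56.2%, 56.6% and 54.0% of exons not called. The share among lowered exons differed between LUC7L2 and LUC7L3 (Fisher's exact p 2.172e-38, adjusted 1.629e-37 over 15 shares compared) and between LUC7L and LUC7L3 (exact adjusted p 3.999e-38), but not detectably between LUC7L and LUC7L2 (exact adjusted p 0.174). The test takes the sets as separate, but 693 lowered exons were shared by LUC7L and LUC7L2, which leaves little room for a difference. G as the last exon base was found in 89.4%, 87.2% and 59.0% of the exons lowered by LUC7L2, LUC7L and LUC7L3.

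The exon-side score, added after the data were seen, averaged 0.772 log2 units in higher and 2.12 in lower exons for LUC7L, a difference of -1.34. For LUC7L2 the means were 0.637 and 2.24 (difference -1.60), and for LUC7L3 3.13 and -0.0724 (difference 3.20). Each had a permutation p of 1e-05, the smallest the draws can give. At the upstream exon, whose site is used in both forms, the differences were -0.00656 (permutation p 0.972), -0.184 (0.454) and 0.601 (0.106). The SRSF6 exon lowered by all 3 proteins ends in GAT, the USP10 exon lowered by LUC7L2 in CAG, the CAP2 exon lowered by LUC7L3 in GTG and the ZDHHC16 exon raised by LUC7L3 in CAG.

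**Figure D2:**
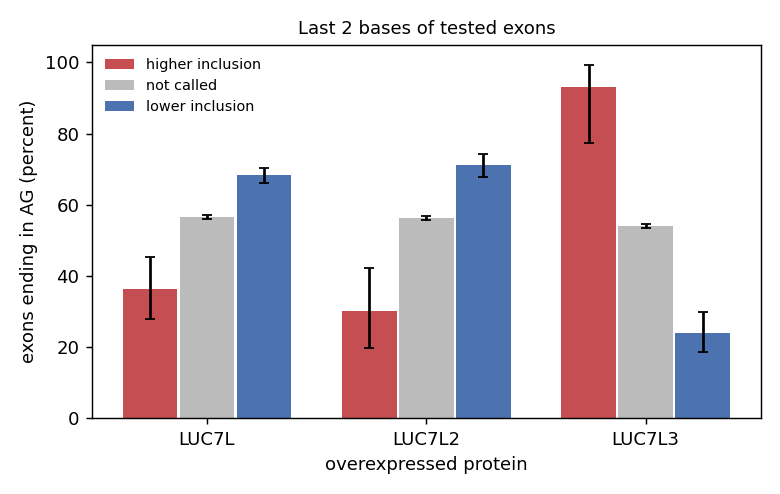
Bars give the percentage of exons ending in AG among exons with higher inclusion (red), not called (grey) or with lower inclusion (blue) after each overexpression, and black lines exact 95% intervals. Lowered exons sat at 68.2% and 71.1% for LUC7L and LUC7L2 and at 23.9% for LUC7L3.

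Tested directly, LUC7L3 and LUC7L2 cells differed at 1198 of 36788 exons, 859 higher and 339 lower with LUC7L3. STOML1 stood at 85.2% ± 7.67 with LUC7L3 and 39.2% ± 11.4 with LUC7L2 (SD, n = 3; FDR 1.16e-07; chromosome 15, 73984659 to 73984871, coding), LRRC27 at 61.2% ± 13.8 and 15.2% ± 8.89 (FDR 2.32e-06) and CHMP4A, an ESCRT-III subunit, at 96.5% ± 5.99 and 48.8% ± 12.1 (FDR 0.000356). In the other direction AKAP8, a nuclear anchor of protein kinase A, stood at 17.1% ± 2.93 and 60.9% ± 17.3 (FDR 0.003; chromosome 19, 15374603 to 15374635, coding). PRPF39 differed most within the U1 list, at 55.5% ± 5.14 and 19.8% ± 1.18 (FDR 1.15e-29). The U1 list had differences in 6 of 18 genes (7 adjusted over the list alone; exact adjusted p 0.0437), but without the transfected genes, left out after this was seen, in 5 of 16 with an exact adjusted p of 0.1086. Chromatin regulators differed in 19 of 73 (19 adjusted over the list alone; exact adjusted p 0.000937), 16 with higher and 4 with lower exons. Of the exons higher with LUC7L3, 79.9% ended in AG (exact interval 77.1 to 82.6), of those lower 14.5% (10.9 to 18.7) and of the others 54.9%. With values centred on the median exon, which moved by 0.16, the split was 596 higher and 517 lower, and in chromatin regulators 12 genes against 7. Centred on shared exons it was 610 and 509, and again 12 genes against 7. The limma fit called 0 (6378 at its unadjusted p under 0.05). Without a read filter the moderated test called 0 (8183 at unadjusted p under 0.05), and with at least 1 read of each form 1278.

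LUC7L3 against LUC7L gave 2357 of 38856 exons, 1976 higher and 381 lower with LUC7L3. Relative to the median exon, which moved by 0.43, 853 were higher and 935 lower, and relative to shared exons, which moved by 0.34, 1039 and 792. The limma fit called 829, and the moderated test 1 without a read filter but 2504 with at least 1 read of each form. CEP97 stood at 97.8% ± 1.91 with LUC7L3 and 45.5% ± 13.1 with LUC7L (FDR 5.64e-16), DNAH1, an axonemal dynein, at 89.9% ± 2.90 and 36.2% ± 15.4 (FDR 0.000642), and AKAP8 at 17.1% ± 2.93 and 71.8% ± 12.1 (FDR 3.52e-05). Centrosome genes differed in 28 of 68 (27 adjusted over the list alone; exact adjusted p 3.865e-05) and chromatin regulators in 30 of 74 (32 adjusted over the list alone; same exact adjusted p). Respiratory chain genes differed in 4 of 73 (4 adjusted over the list alone), fewer than the 17.5% of other genes (exact adjusted p 0.0220). ATP5PB of the ATP synthase stood at 96.7% ± 0.170 and 73.9% ± 10.9. LUC7L2 against LUC7L gave 151 of 38536 exons, 144 higher and 7 lower with LUC7L2, and no list differed detectably from other genes. CDK10 stood at 76.5% ± 12.7 with LUC7L2 and 32.1% ± 7.77 with LUC7L (FDR 0.017), and PRC1, a protein of the spindle midzone, at 56.6% ± 4.43 and 66.8% ± 4.45 (FDR 6.75e-05). That count moved to 45 relative to the median exon, where 25 higher and 20 lower left no clear direction (exact binomial p 0.5515), to 52 relative to shared exons (38 higher and 14 lower), to 1 without a read filter (201 with at least 1 read of each form), to 95 and 46 without the second and the third LUC7L2 library and to 26 and 237 without the first and the third LUC7L library, and limma called 2.

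LUC7L and LUC7L2 lowered 693 exons in common among 29950 tested in both, against 51.5 for independent lists, and raised 35, with 0 called in opposite directions. LUC7L and LUC7L3 shared 84 lowered exons (13.5 for independent lists) and LUC7L2 and LUC7L3 54 (5.69). Unchanged groups simulated with shared, also simulated, controls had 0 such exons in common in each case. The PSI differences covaried at 27.7 squared points for LUC7L and LUC7L2 (simulated 7.79), 10.3 for LUC7L and LUC7L3 (7.68) and 9.41 for LUC7L2 and LUC7L3 (7.57). Their correlations were 0.77 (simulated 0.52), 0.34 (0.52) and 0.36 (0.52). Both pairs with LUC7L3 thus lay above the simulated covariance but below the simulated correlation. The 3 controls could not be split into parts of at least 2, so part of the excess may come from the shared controls. Exons called in opposite directions, named after their values were seen, were in PRPF39, TONSL and RBM5. TONSL, a replication repair factor, stood at 46.5% ± 6.69 with LUC7L, 50.8% ± 4.63 with LUC7L2 and 76.9% ± 3.28 with LUC7L3, against 62.5% ± 2.08 in control cells. RBM5, a splicing factor, stood at 82.7% ± 2.26 with LUC7L2 and 54.4% ± 2.75 with LUC7L3, against 70.7% ± 4.13.

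In seedlings, the single luc7a and luc7b mutants had few called exons at this depth. AT5G56140, called lower in luc7b-1, stood at 37.8% ± 2.71 against 54.2% ± 4.47 (SD, n = 3; FDR 6.33e-05; chromosome 5, 22726610 to 22726755 of TAIR10, within the coding sequence). It was the single call among 1384 exons, of which 121 had an unadjusted p under 0.05, and limma called 0. In luc7a-1 the quasi-binomial test with limma moderation called 0 of 1385 exons (118 at unadjusted p under 0.05) and in luc7a-2 0 of 1444 (123), and limma on logit PSI called 0 in both. By the FDR of the authors' table the calls were 59 in luc7a-1, 67 in luc7a-2 and 65 in luc7b-1. DYL1, a dormancy-associated gene, stood at 51.6% in luc7a-1, 49.9% in luc7a-2 and 44.3% in luc7b-1, against 48.0% ± 2.65 in Col0. Between the luc7a alleles, 2 of 1315 exons differed, both lower in luc7a-2: AT5G56140 at 46.1% ± 8.29 against 60% ± 4.66 and AT1G29030 at 44.8% ± 8.78 against 89.1% ± 3.79 (FDR 0.0297 each). This count did not hold: limma called 0 (57 at its unadjusted p under 0.05), as did the moderated test on either centring (71 and 69) and without a read filter (131), and leaving out any single library gave 0 or 1.

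In luc7rl-1, AT5G05435 fell from 87.9% ± 2.38 in Col0 to 47.4% ± 8.99 (SD, n = 3; FDR 7.28e-05; chromosome 5, 1606960 to 1607060, outside the coding sequence). HHP4 (AT4G37680), a heptahelical membrane protein, fell from 78.8% ± 2.75 to 40.6% ± 12.5 (FDR 0.000516; chromosome 4, 17700986 to 17701044), and RVE1 (AT5G17300), a MYB factor tied to the circadian clock, from 84.2% ± 5.26 to 69.2% ± 1.12 (FDR 0.000323; chromosome 5, 5691551 to 5691612, coding). DYL1 (AT1G28330, chromosome 1, 9934451 to 9934566, partly coding) fell from 48.0% ± 2.65 to 29.9% ± 3.03 (FDR 1.36e-30). The single rise was in TGA6 (AT3G12250), a bZIP factor of salicylic acid signalling, from 0% in all 3 Col0 libraries to 16.6% ± 6.89 (FDR 0.0324). Of 1591 exons, 1 was called higher and 35 lower, with 339 at an unadjusted p under 0.05, while limma called 0. Clock genes had 1 call in 5 (1 adjusted over the list alone). The median exon moved by -0.74 in log2 odds and that of shared exons by -0.26, and centring on the former gave 10 higher and 8 lower, on the latter 1 and 21. The count was 6, 14 and 18 without each luc7rl-1 library and 23 and 22 without the second and the third Col0 library.

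The double mutant luc7a-1 luc7b-1 showed calls in both directions. AT1G67900 rose from 18.0% ± 5.32 to 72.3% ± 11.9 (SD, n = 3; FDR 3.24e-06; chromosome 1, 25467032 to 25467159, outside the coding sequence), MAF3 (AT5G65060), a MADS-box repressor of flowering, from 49.0% ± 12.5 to 79.8% ± 2.91 (FDR 1.19e-05; chromosome 5, 25989671 to 25989728, coding), and DYL1 to 72.6% ± 5.05 (FDR 1.27e-18). AT5G26110 fell from 89.9% ± 8.20 to 45.6% ± 1.64 (FDR 3.53e-08; chromosome 5, 9119290 to 9119370, partly coding) and AT5G06180 from 81.9% ± 3.26 to 28.0% ± 17.2 (FDR 0.00236). With the other luc7a allele, luc7a-2 luc7b-1, AT5G26110 fell to 47.5% ± 8.48 (FDR 1.28e-05) and AT1G67900 rose to 53.2% ± 8.46 (FDR 0.000403), while DYL1 stood at 55.7% ± 0.684 and was not called. There the only other rise was in AT4G27610, from 0% in all 3 Col0 libraries to 21.7% ± 19.7 (FDR 0.0387).

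Of 1594 exons in luc7a-1 luc7b-1, 18 were called higher and 62 lower (limma 21), and of 1686 in luc7a-2 luc7b-1, 2 and 24, with 430 at an unadjusted p under 0.05 and 0 by limma. Flowering genes had 1 call in 3 tested in the former (1 adjusted over the list alone). Relative to the median exon, which moved by -0.54 and -0.77, the splits were 52 higher and 31 lower, and 36 and 10; relative to shared exons, which moved by 0.23 in luc7a-1 luc7b-1, 10 and 82, and by -0.08 in luc7a-2 luc7b-1, 2 and 21. The counts were 34, 20 and 29 without each luc7a-1 luc7b-1 library, 53 without the third Col0 library, and 10, 13 and 10 without each luc7a-2 luc7b-1 library. In the direct test of the alleles 18 of 1666 exons differed, 3 higher and 15 lower in luc7a-2 luc7b-1. The 3, named after their values were seen, were a pair of overlapping exons of AT4G35785 (33.4% ± 7.83 against 19.1% ± 0.600 for the longer) and one of VAB2, a subunit of the vacuolar ATPase (60.1% ± 8.36 against 41.8% ± 4.02). DYL1 (FDR 2.51e-16) and RRC1, a splicing factor of red light responses (69.2% ± 2.82 against 91.7% ± 3.77), were among the lower ones. That count was 8 and 7 without the first and the second luc7a-2 luc7b-1 library and 8 without the third luc7a-1 luc7b-1 library, limma called 0, and the split was 10 higher and 9 lower relative to the median exon and 11 and 8 relative to shared exons. Without a read filter the moderated test called 0 (303 at unadjusted p under 0.05), and with at least 1 read of each form 28.

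In the double mutants that carry luc7rl-1, HHP4 fell to 37.0% ± 6.16 in luc7a-1 luc7rl-1 (SD, n = 3; FDR 0.000658) and to 46.4% ± 9.45 in luc7b-1 luc7rl-1 (FDR 0.0143), and DYL1 to 31.5% ± 3.25 and 31.9% ± 2.89 (FDR 1.73e-32 in the latter). In luc7a-1 luc7rl-1, HSFA2 (AT2G26150), a heat stress factor and the only call in 2 tested abscisic acid and stress genes (1 adjusted over the list alone), fell from 60.8% ± 5.95 to 12.9% ± 14.1 (FDR 0.0274; chromosome 2, 11136246 to 11136276, coding). KAT5 (AT5G48880), a thiolase of fatty acid breakdown, rose from 44.9% ± 10.8 to 86.5% ± 15.3 (FDR 0.0297), its overlapping longer exon being the other rise. In luc7b-1 luc7rl-1, AT5G05435 fell to 49.7% ± 11.5, and the 3 rises were AT5G25520 (from 18.5% ± 4.36 to 42.6% ± 5.75), AT2G41060 (from 20.2% ± 3.45 to 42.4% ± 4.43) and AT5G45190 (from 80.4% ± 12.2 to 93.9% ± 4.57). Of 1698 exons 2 were called higher and 35 lower in luc7a-1 luc7rl-1, and of 1625, 3 and 30 in luc7b-1 luc7rl-1, with 339 and 313 at an unadjusted p under 0.05; limma called 0 and 1. Relative to the median exon, which moved by -0.76 and -0.66, the splits were 26 higher and 11 lower, and 16 and 7. On shared exons, which moved by -0.08 and -0.10, they were 3 and 30, and 3 and 26. Leaving out any single library lowered the first count to between 8 and 24, and the second was 18 without the second luc7b-1 luc7rl-1 library, 9 without the third one, and 18 and 17 without the second and the third Col0 library.

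The mutant in all 3 genes, called the triple mutant here, carries luc7a-2 with luc7b-1 and luc7rl-1. It had the most calls among the plants. PAC (AT2G48120), a chloroplast protein needed for greening, fell from 98.6% ± 1.89 to 26.5% ± 3.21 (SD, n = 3; FDR 3.22e-07; chromosome 2, 19680471 to 19680557, coding). BNS (AT1G73177), a subunit of the anaphase-promoting complex, fell from 92.9% ± 9.92 to 19.7% ± 5.09 (FDR 0.000104; chromosome 1, 27516927 to 27517194, partly coding), AT1G02960 from 90.8% ± 3.19 to 33.3% ± 1.65 (FDR 0.000427) and AT4G37110 from 93.6% ± 7.12 to 37.8% ± 8.66 (FDR 0.000399). VLN4, an actin-binding villin, went from 100% in all 3 Col0 libraries to 35.9% ± 22.2 (FDR 0.0113). AT2G41060 rose to 68.8% ± 3.00 (FDR 6.03e-05; chromosome 2, 17128775 to 17129205, outside the coding sequence), AT5G25520 to 59.0% ± 6.38 (FDR 5.13e-05), KAT5 to 86.2% ± 21.1 (FDR 0.0117) and GK-1, a guanylate kinase, from 17.6% ± 5.59 to 51.4% ± 6.02 (FDR 0.0113). Among exons seen in other mutants, HHP4 stood at 45.6% ± 8.10, AT5G26110 at 48.5% ± 1.39 and AT5G05435 at 49.5% ± 4.85, all called lower.

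Of 2585 exons 39 were called higher and 285 lower, or 88.0% lower, and limma called 257. The median exon moved by -2.89 in log2 odds, and relative to it 346 exons were higher and 18 lower. Of the tested exons 35.9% had no skipping read in Col0, so their odds there rested on a floor below a whole read. These exons passed the read filter only through skipping reads of the triple mutant. The shift of the median exon thus depends in part on this floor and filter. Relative to exons tested in every genotype, which moved by -0.35, 51 were higher and 235 lower. In the fixed lists the U1 protein gene PRP39 fell from 15.3% ± 2.58 to 3.50% ± 2.17 (FDR 0.000704; 1 call in 2 tested), RVE1 to 53.3% ± 8.81 (FDR 0.000121; 1 in 7 clock genes) and MAF3 rose to 70.1% ± 2.92 (FDR 0.0193; 1 in 4 flowering genes), where centring on the median exon turned the direction of PRP39, RVE1 and DYL1. Called genes numbered 0 of 7 SR proteins, 0 of 6 glycine-rich, PTB and UBP1 proteins, 0 of 4 photosynthesis, 0 of 3 light signalling, 0 of 1 stress and 0 of 1 decay genes by the test with limma moderation, and no root gene was testable. The counts adjusted over the list alone were the same, and the exact adjusted p was 1 for each list. Among all tested exons 1187 had an unadjusted p under 0.05.

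The bases of the 5' splice site at lowered exons differed between plant genotypes. In luc7a-1 luc7b-1 and luc7a-2 luc7b-1, 33.9% and 20.8% of lowered exons had G as the last exon base and 82.0% and 91.7% had G at intron position 5. In luc7rl-1 the shares were 85.7% and 14.3%, in luc7a-1 luc7rl-1 88.6% and 23.5%, in luc7b-1 luc7rl-1 83.3% and 10.3%, and in the triple mutant 69.8% and 49.5%. Among exons not called in these 6 mutants the shares were 67.2% to 73.1% and 46.2% to 55.5%, and in the triple mutant 73.1% and 49.4%. The difference between luc7rl-1 and luc7a-2 luc7b-1 had an exact adjusted p of 5.907e-09 for the intron base and 1.295e-06 for the exon base, and that between luc7rl-1 and luc7a-1 luc7b-1 1.886e-10 and 1.295e-06. The luc7a-1 luc7b-1 and luc7a-2 luc7b-1 mutants did not differ detectably (exact adjusted p 0.358 and 0.347), but they shared 14 lowered exons, which the test counts in both sets. The neighbouring upstream exons of these lowered exons also differed, in a test added after the data were seen. G at intron position 5 stood there in 28.6% for luc7rl-1, 66.7% for luc7a-2 luc7b-1 (exact adjusted p against luc7rl-1 0.0211) and 66.1% for luc7a-1 luc7b-1 (0.00367), and G as the last exon base in 91.4%, 70.8% (0.1105) and 67.7% (0.0236). The gaps between genotypes were thus smaller there but ran the same way, so the differences are not shown to be confined to the skipped exon's own site. The AT5G26110 exon, lowered in both of these, ends in GCT and is followed by GTAAGT, and the HHP4 exon, lowered with luc7rl-1, ends in TAG and is followed by GTAATG.

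The planned balance of higher minus lower exons had few higher exons to compare. It was -1.59 log2 units in luc7a-1 luc7b-1 (permutation p 0.05495, but 1e-05 to 0.2159 under 6 alternatives, 4 of them under 0.05), -4.30 in luc7a-2 luc7b-1 (exact p 0.05538, 2 higher exons; 1e-05 to 0.1607 under 5 alternatives, 2 of them under 0.05), 1.40 in luc7b-1 luc7rl-1 (exact p 0.3204), 0.137 in luc7rl-1 (exact p 0.9444, 1 higher exon) and -0.296 in the triple mutant (permutation p 0.5595). The same planned balance at the upstream exon was -0.781 in luc7a-1 luc7b-1 (permutation p 0.4154) and 0.719 in the triple mutant (0.1706), and in the other 4 mutants, with 1 to 3 higher exons, exact p was 0.3183 to 0.3948. At the exon's own site in luc7a-1 luc7rl-1 it was 7.19, but the 2 higher exons overlap and share 1 splice site, that of KAT5, so no p-value is given. Compared with exons not called, a contrast added after the data were seen, lowered exons had a balance higher by 2.18 in luc7a-1 luc7b-1 (permutation p 2e-05) and 3.00 in luc7a-2 luc7b-1 (1e-05, the smallest the draws can give). The same contrast was -0.587 in luc7rl-1 (0.2668), -0.322 in luc7a-1 luc7rl-1 (0.5467), -0.0112 in luc7b-1 luc7rl-1 (0.9851) and 0.286 in the triple mutant (0.1397).

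**Figure D3:**
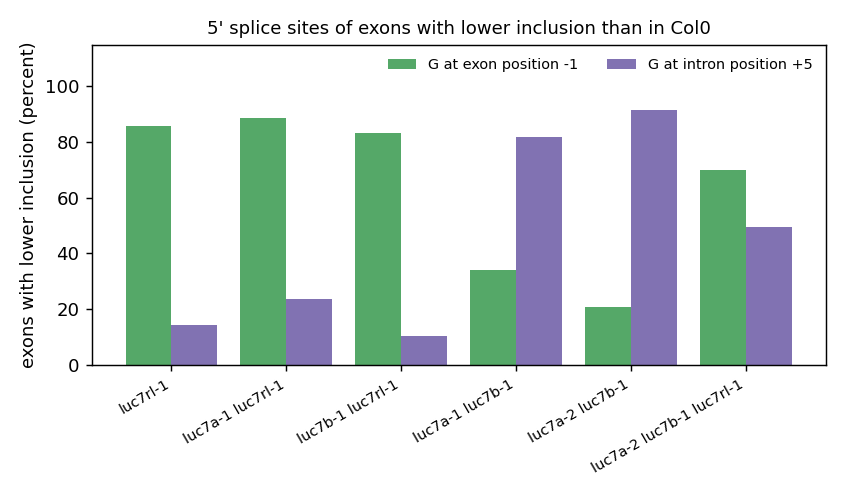
Bars give the percentage of lowered exons with G as the last exon base (green) and with G at intron position 5 (violet) for each mutant with 10 or more calls, without error bars. Mutants in LUC7A and LUC7B sat at 82.0% and 91.7% for the intron base and luc7rl-1 at 14.3%, and the triple mutant at 49.5%, against 49.4% of its exons not called.

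Compared directly, luc7rl-1 and luc7a-2 luc7b-1 differed at 104 of 1664 exons, 51 higher and 53 lower in luc7rl-1. DYL1 stood at 29.9% ± 3.03 in luc7rl-1 and 55.7% ± 0.684 in luc7a-2 luc7b-1 (SD, n = 3; FDR 8.1e-143). Clock genes differed in 3 of 4 tested (3 adjusted over the list alone; exact adjusted p 0.0106). RVE1 was lower in luc7rl-1, at 69.2% ± 1.12 against 84.4% ± 8.15, while PRR7, a clock repressor, was higher at 96.5% ± 1.23 against 84.2% ± 7.89 and AT5G64170 higher at 64.6% ± 21.5 against 23.9% ± 9.83. The triple mutant differed from luc7a-2 luc7b-1 at 210 of 2109 exons, 34 higher and 176 lower. PAC stood at 26.5% ± 3.21 against 97.3% ± 3.91 (FDR 8.73e-27), BNS at 19.7% ± 5.09 against 86.6% ± 15.8 (FDR 1.65e-06) and AT5G45190 at 97.5% ± 4.29 against 52.7% ± 12.3 (FDR 1.99e-06). After centring on the median exon, which moved by -0.77, the latter split was 93 higher and 101 lower, and on shared exons, which moved by -0.31, 49 and 140. PAC also fell in luc7rl-1 (78.6% ± 6.07), luc7a-1 luc7rl-1 (75.3% ± 6.86) and luc7b-1 luc7rl-1 (76.1% ± 5.03). The limma fit called 19 and 109 of these differences, and leaving out the second luc7rl-1 library gave 69 for the former. Without a read filter the moderated test called 0 (465 at unadjusted p under 0.05) and 70, and with at least 1 read of each form 58 higher and 57 lower for the former and 213 for the latter.

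The luc7rl-1 mutant shared 17 lowered exons with luc7b-1 luc7rl-1 (0.769 for independent lists), 15 with luc7a-1 luc7rl-1 (0.865) and 23 with the triple mutant (4.88), but 0 with luc7a-1 luc7b-1 and 1 with luc7a-2 luc7b-1 (0.454). The luc7a-1 luc7b-1 and luc7a-2 luc7b-1 mutants shared 14 lowered and 1 higher (0.969 for independent lowered lists). Simulated unchanged groups shared 0 lowered exons in each pair. PSI differences covaried at 40.4 squared points for luc7rl-1 and luc7b-1 luc7rl-1 (simulated 15.6) and 51.7 for luc7a-1 luc7b-1 and luc7a-2 luc7b-1 (14.6). The covariance was only 8.47 for luc7rl-1 and luc7a-2 luc7b-1 (14.7) and 10.5 for luc7rl-1 and luc7a-1 luc7b-1 (14.1). The 3 Col0 libraries are shared by all, and could not be split. DYL1 was called higher in luc7a-1 luc7b-1 and lower in luc7rl-1, both of its double mutants and the triple, and RRC1 higher in luc7a-1 luc7b-1 (91.7% ± 3.77 against 74.8% ± 7.39) and lower in luc7a-1 luc7rl-1 (53.6% ± 12.2).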

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

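The tests of depth, of centring on the median exon, of the upstream exon's bases, of the luc7a alleles at equal total reads and of other library splits for the 12 comparisons with a control were chosen after the results they bear on were seen. Centring on shared exons was added after the data were seen, with its expected outcome written before its result. The comparison by control inclusion was chosen before its result was seen.

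What drew attention was that the responses of groups that share a control differed when tested against each other. LUC7L3 and LUC7L2 overexpression differed at 1198 exons, LUC7L3 and LUC7L at 2357, and LUC7L2 and LUC7L at 151. Without a read filter these counts were 0 (8183 at unadjusted p under 0.05), 1 and 1, with at least 1 read of each form 1278, 2504 and 201, and by limma 0 (6378), 829 and 2. In seedlings the triple mutant differed from luc7a-2 luc7b-1 at 210 exons, luc7rl-1 from luc7a-2 luc7b-1 at 104, luc7a-2 luc7b-1 from luc7a-1 luc7b-1 at 18 and luc7a-2 from luc7a-1 at 2, a count that limma and both centrings put at 0 (57, 71 and 69 at unadjusted p under 0.05). Among the larger differences were CEP97 (97.8% ± 1.91 with LUC7L3, 45.5% ± 13.1 with LUC7L) and AKAP8 (17.1% ± 2.93 with LUC7L3, 71.8% ± 12.1 with LUC7L) in cells and PAC (26.5% ± 3.21 in the triple mutant, 97.3% ± 3.91 in luc7a-2 luc7b-1) in seedlings.

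The first pattern weighed was that exons lowered by LUC7L2 ended in AG far more often than exons lowered by LUC7L3, by 47.2 percentage points. Exons that differ in inclusion in control cells could differ in their ends, but within 10 classes of control inclusion the gap was 47.4 points (95% bootstrap interval 40.9 to 53.9), so this does not account for it. Nor was the gap seen at the sites of the neighbouring upstream exons, which differed by -0.560 points (-7.71 to 6.79). Base composition of the region beyond these exon ends was not measured and stays open. One hypothesis left is that the proteins act on sites of different makeup, but it was found and tested on the same libraries. The groups also differed in junction reads of the transfected gene, 38456 ± 7927 RPM for LUC7L2 and 4935 ± 532 for LUC7L3. These reads depend on each gene's listed events and do not measure amounts between genes. Whether unequal amounts of the proteins played a part was not tested. The limma fit, which called 0 exons for both proteins, could not show the pattern.

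The second pattern was that most called exons had lower inclusion. Most junction reads of the controls were inclusion reads, and an exon within 10 points of full inclusion can only be called lower. The minimum of skipping reads over all libraries also admits exons through the group that skips more. How much of the excess these limits account for was not measured. Thinning all libraries to equal total reads left 94.9% of LUC7L calls lower (93.8 to 95.8) and 85.3% in the triple mutant (80.3 to 89.4), which argues against unequal totals, while unequal reads per exon were not tested. For LUC7L, centring on the median exon, which itself pulls the directions towards balance, left 50.7% lower (48.3 to 53.1), so a shift of nearly all tested exons stays open and is not shown. Centring on exons tested in every comparison left 69.6% (67.2 to 71.9), and a shared shift cannot be told apart from lowering of a set of exons, because both move the same exons. In the triple mutant the 4.95% lower calls (2.96 to 7.70) after centring on the median exon leave this open, as 35.9% of tested exons had no skipping read in Col0 and no fit left them out. After centring on shared exons 82.2% were lower (77.2 to 86.4), the outcome set beforehand as against a shared shift. But exons without a skipping read in Col0 stayed in that test and could only be called lower, so it does not decide the question.

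The third pattern was that luc7a-1 luc7b-1 had 80 calls and luc7a-2 luc7b-1 26, although both are labelled as mutants of LUC7A and LUC7B, but by the FDR of the authors' table the counts were 185 and 179. Leaving out each luc7a-1 luc7b-1 library in turn gave 34, 20 and 29 calls, the last without the third library, which was deep (6.83 M junction reads), and each luc7a-2 luc7b-1 library 10, 13 and 10. On events listed in every table the counts were 66 and 25, and 51 and 25 after thinning to equal totals, a ratio of 2.04 (1.24 to 3.44). This interval rests on the counts alone, takes called exons as independent and holds no spread between libraries. It is wide, and reads per exon were not equalised. A share of the gap due to depth thus cannot be told apart from a difference between the mutants. The direct test called 23 exons between them on events listed in every table and 14 after thinning to equal totals, so fewer were called at equal totals. Those left could come from a difference between the luc7a alleles or in the background of the lines, and the labels name only the alleles. In the test without thinning DYL1 was called, at 72.6% ± 5.05 in luc7a-1 luc7b-1 and 55.7% ± 0.684 in luc7a-2 luc7b-1.

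Each comparison of 3 with 3 libraries allows 10 splits, too few for a share under 0.05. The other splits mix libraries of both groups, so a real difference becomes spread within groups and lowers their calls. Their low counts therefore do not measure how many calls arise by chance. The real split had the most calls, 1 split of 10, in every comparison except luc7a-1 and luc7a-2 (10 of 10 splits had at least the real count of 0), luc7b-1 (2 of 10) and luc7a-2 against luc7a-1 (2 of 10). The highest other split gave 0 calls for LUC7L, 2 for LUC7L2, 26 for LUC7L3, 5 for luc7a-1, 1 for luc7a-2, 1 for luc7b-1 and 1 for luc7rl-1, beside real counts of 2204, 882, 264, 0, 0, 1 and 36. It gave 0 for luc7a-1 luc7b-1 (real 80), 1 for luc7a-1 luc7rl-1 (37), 0 for luc7a-2 luc7b-1 (26), 2 for luc7b-1 luc7rl-1 (33) and 0 for the triple mutant (324). In the direct tests it gave 0 for LUC7L3 against LUC7L2 and against LUC7L, 58 for LUC7L2 against LUC7L (real 151), 0 for the triple mutant against luc7a-2 luc7b-1, and 3 for each of luc7a-2 against luc7a-1, luc7a-2 luc7b-1 against luc7a-1 luc7b-1 and luc7rl-1 against luc7a-2 luc7b-1.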

How the results depend on the processing

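Thinning, both kinds of centring, the read filter that asks for both forms, the exon-side score, the comparison of lowered with other exons and the leaving out of transfected genes or of exons called in another mutant were chosen after the data were seen. No paired analysis was possible because the columns carry no replicate numbers. DESeq2 was not run, although the split reads of each library are plain counts. At 20 reads per library 19 counts and 296 other results were unchanged, a count being unchanged if it moved by no more than 1.5 times. For each change below the cause was not tested unless it is named. Depth sets how many exons can be tested, and simulated changes of 10 points at exons of middling inclusion were mostly missed in each comparison.

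At a size threshold of 5 points the calls were 3957 for LUC7L, 1533 for LUC7L2, 534 for LUC7L3, 44 for luc7a-2 luc7b-1, 2314 for LUC7L3 against LUC7L2, 4301 for LUC7L3 against LUC7L and 409 for LUC7L2 against LUC7L. At 20 points they were 656 for LUC7L, 228 for LUC7L2, 61 for LUC7L3, 0 for luc7b-1, 12 for luc7rl-1, 45 for luc7a-1 luc7b-1, 17 for luc7a-1 luc7rl-1, 15 for luc7a-2 luc7b-1, 16 for luc7b-1 luc7rl-1 and 179 for the triple mutant. For the direct tests 20 points gave 308 for LUC7L3 against LUC7L2, 640 for LUC7L3 against LUC7L, 21 for LUC7L2 against LUC7L, 125 for the triple mutant against luc7a-2 luc7b-1, 1 for luc7a-2 against luc7a-1, 6 for luc7a-2 luc7b-1 against luc7a-1 luc7b-1 and 57 for luc7rl-1 against luc7a-2 luc7b-1. These follow from the thresholds. The share of higher exons in luc7rl-1 against luc7a-2 luc7b-1, 49.0% at 10 points, was 50.7% at 5 and 54.4% at 20.

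With every listed event the calls were 3481 for LUC7L and 229 for LUC7L2 against LUC7L, where an exon counts once per listed event. On logit PSI limma called 977 for LUC7L, 0 for LUC7L2, 0 for LUC7L3, 0 for luc7b-1, 0 for luc7rl-1, 21 for luc7a-1 luc7b-1, 0 for luc7a-1 luc7rl-1, 0 for luc7a-2 luc7b-1 and 1 for luc7b-1 luc7rl-1. In direct tests limma called 0 for LUC7L3 against LUC7L2, 829 for LUC7L3 against LUC7L, 2 for LUC7L2 against LUC7L, 109 for the triple mutant against luc7a-2 luc7b-1, 0 for luc7a-2 against luc7a-1, 0 for luc7a-2 luc7b-1 against luc7a-1 luc7b-1, and 19 for luc7rl-1 against luc7a-2 luc7b-1 with 73.7% higher. Of the other results limma kept 108 and left 226 below its threshold, and 1, the share just given, turned. With the FDR of the authors' deposited table the calls were 1601 for LUC7L2, 782 for LUC7L3, 59 for luc7a-1, 67 for luc7a-2, 65 for luc7b-1, 139 for luc7rl-1, 185 for luc7a-1 luc7b-1, 141 for luc7a-1 luc7rl-1, 179 for luc7a-2 luc7b-1 and 142 for luc7b-1 luc7rl-1.

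On events listed in every table luc7a-1 luc7b-1 had 66 calls, luc7a-1 luc7rl-1 32 and LUC7L2 against LUC7L 151, and after thinning these to equal total reads 51, 24 and 65, so part of the first 2 moves came with the choice of events. With thinning 263 other results held and 46 fell below the threshold. Without any minimum of each form the direct tests gave 0 for LUC7L3 against LUC7L2, 1 for LUC7L3 against LUC7L, 1 for LUC7L2 against LUC7L, 70 for the triple mutant against luc7a-2 luc7b-1, 0 for luc7a-2 against luc7a-1, 0 for luc7a-2 luc7b-1 against luc7a-1 luc7b-1 and 0 for luc7rl-1 against luc7a-2 luc7b-1. Where both forms had to be seen, they gave 28 for luc7a-2 luc7b-1 against luc7a-1 luc7b-1, and 50.4% of calls higher in luc7rl-1 against luc7a-2 luc7b-1.

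Centred on the median exon, the calls were 18 in luc7rl-1, 46 in luc7a-2 luc7b-1, 45 in LUC7L2 against LUC7L and 0 in luc7a-2 against luc7a-1. The share of higher exons turned to 55.6% in luc7rl-1, 62.7% in luc7a-1 luc7b-1, 70.3% in luc7a-1 luc7rl-1, 78.3% in luc7a-2 luc7b-1, 69.6% in luc7b-1 luc7rl-1, 95.1% in the triple mutant, 47.7% in LUC7L3 against LUC7L, 52.6% in luc7a-2 luc7b-1 against luc7a-1 luc7b-1 and 54.9% in luc7rl-1 against luc7a-2 luc7b-1. Single exons that turned from lower to higher were RNPS1 after LUC7L (0.12 points) and, in the triple mutant, PRP39 (1.13), RVE1 (11.4), DYL1 (23.7), BGLU9 (6.41) and AT5G22620 (27.9). Of results other than counts 246 held, 87 fell below the threshold and 16 turned. Centred on shared exons, the calls were 22 in luc7rl-1, 52 in LUC7L2 against LUC7L and 0 in luc7a-2 against luc7a-1, and the share of higher exons was 57.9% in luc7a-2 luc7b-1 against luc7a-1 luc7b-1 and 55.9% in luc7rl-1 against luc7a-2 luc7b-1. Here 289 held, 57 fell below the threshold and 3 turned. Without the transfected genes 1 gene list, chromatin regulators, stood apart in LUC7L3 against LUC7L2, and the U1 list no longer did. The PSI difference by splice site balance in the triple mutant's lowered exons, -7.88 points, was -0.317 (permutation p 0.861) without exons called in another mutant.

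The balance of higher minus lower exons in luc7rl-1 was -0.0543 at 5 points, -0.4 by match counts and -0.259 over the shorter positions. In luc7a-1 luc7b-1, where p was 0.05495, it passed 0.05 at -1.54 at 5 points (p 0.04375), -1.13 by match counts (0.00164), -2.26 over the shorter positions (0.0023) and -3.67 centred on the median exon (1e-05), but not on shared exons (0.2159) or by limma (0.119). In luc7a-2 luc7b-1, where p was 0.05538, it passed at -5.53 centred on the median exon (1e-05) and -4.94 on shared exons (0.02767), but not by match counts (0.1262), over the shorter positions (0.06462) or at 5 points (0.1607). The balance was -0.0132 in luc7b-1 luc7rl-1 at 5 points, 0.0476 in the triple mutant by match counts and 0.220 in luc7a-1 luc7rl-1 centred on the median exon. For lowered against other exons it was 0.0863 in luc7a-1 luc7rl-1 centred on the median exon and 0.229 in luc7b-1 luc7rl-1 centred on shared exons.

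Leaving out each library in turn gave 1561 to 2235 calls for LUC7L, 583 to 1095 for LUC7L2, 122 to 414 for LUC7L3, 6 to 33 for luc7rl-1, 20 to 82 for luc7a-1 luc7b-1, 8 to 24 for luc7a-1 luc7rl-1, 10 to 23 for luc7a-2 luc7b-1, 9 to 25 for luc7b-1 luc7rl-1 and 243 to 319 for the triple mutant. It gave 917 to 1214 for LUC7L3 against LUC7L2, 1726 to 2391 for LUC7L3 against LUC7L, 26 to 237 for LUC7L2 against LUC7L, 156 to 213 for the triple mutant against luc7a-2 luc7b-1, 0 to 1 for luc7a-2 against luc7a-1, 7 to 21 for luc7a-2 luc7b-1 against luc7a-1 luc7b-1 and 69 to 93 for luc7rl-1 against luc7a-2 luc7b-1, where the share of higher exons was 38.7% to 50.6%. The libraries that moved a count by more than 1.5 times are named beside that count in the report, and for luc7a-2 against luc7a-1 each library did so.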

Other observations

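The test of the splice site balance in the triple mutant and both tests of exon length were chosen before their results were seen, and the exons called in opposite directions were picked after theirs were seen. Some genes stood at different levels in sets of mutants. AT5G22620 (chromosome 5, 7518569 to 7518634 of TAIR10, coding) had 80.4% ± 12.9 inclusion in Col0 (SD, n = 3), was called higher in luc7a-1 luc7b-1 at 92.2% ± 1.39 and lower in luc7a-1 luc7rl-1 at 57.7% ± 5.74 and in the triple mutant at 63.4% ± 3.30. HHP2, a relative of HHP4, stood at 86.7% ± 3.37 in Col0 and was called higher in luc7a-1 luc7b-1 at 98.0% ± 1.85 and lower in luc7b-1 luc7rl-1 at 64.9% ± 8.45. BGLU9, a beta-glucosidase, stood at 50.2% ± 4.93 in Col0, 73.7% ± 23.3 in luc7a-1 luc7b-1 and 18.4% ± 2.12 in the triple mutant. AT1G67900 was raised in both mutants of LUC7A and LUC7B but stood at 22.3% ± 3.54 in the triple mutant and 14.6% ± 3.97 in luc7rl-1, against 18.0% ± 5.32 in Col0, neither of them called. Centring on the median exon turned the triple mutant's falls to rises of 27.9 points for AT5G22620 and 6.41 for BGLU9, and left AT5G22620 in luc7a-1 luc7rl-1 (FDR 0.155) and HHP2 in luc7b-1 luc7rl-1 (FDR 0.182) uncalled. Centred on shared exons, the fall of BGLU9 in the triple mutant was called (FDR 0.0018) but not that of AT5G22620 (-12.9 points, FDR 0.121), nor the rises in luc7a-1 luc7b-1 of HHP2, BGLU9 and the AT5G22620 exon given above.

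In human cells exons of single regulators were called, some after more than 1 of the proteins. SRRM1, a splicing coactivator, fell from 22.6% ± 2.88 to 10.2% ± 0.869 after LUC7L (SD, n = 3; FDR 9.14e-11) and 10.4% ± 2.40 after LUC7L2. RBM39, a splicing factor, fell from 32.1% ± 2.73 to 17.8% ± 1.85 after LUC7L. CLK2, a kinase of SR proteins, fell from 58.9% ± 4.58 to 35.8% ± 4.10 after LUC7L and 43.5% ± 6.96 after LUC7L2. CLK1 fell from 84.4% ± 3.09 to 68.0% ± 9.89 after LUC7L3 and 64.5% ± 6.14 after LUC7L. BRD9, a subunit of a SWI/SNF complex, rose from 4.98% ± 2.66 to 15.1% ± 3.20 after LUC7L3 and the demethylase KDM5A from 25.6% ± 6.73 to 40.5% ± 3.84. The DNA repair factor XPA fell from 25.9% ± 4.72 to 7.45% ± 2.33 after LUC7L2 and 8.15% ± 2.14 after LUC7L.

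A hypothesis was that the exons lowered in the triple mutant are a mixture, in which the splice site balance tells those that respond to luc7rl-1 from those that respond to luc7a-2 luc7b-1. Among them, the PSI difference luc7rl-1 minus luc7a-2 luc7b-1 averaged -3.89 points (SD 12) in the 103 exons with the lower balance and 3.99 points (SD 18.2) in the 106 with the higher balance. The difference of -7.88 points had a permutation p of 0.00037, but the set held exons called in luc7rl-1 or luc7a-2 luc7b-1, whose site bases had prompted the test. Without exons called in any other mutant, left out after that result was seen, the difference was -0.317 points (73 and 65 exons; permutation p 0.861). The mixture is thus not shown beyond the exons that prompted it.

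Another hypothesis was that lowered exons keep the reading frame more often than others. Lengths divisible by 3 made up 40.1% of exons lowered by LUC7L against 37.9% of exons not called (Fisher's exact p 0.05067), and 39.6% against 39.8% in the triple mutant (exact p 1). Neither passed the threshold, and neither shows that the shares are equal. Lowered exons had a median length of 157 bases against 120 after LUC7L and 70 against 78 in the triple mutant, differences that were not tested.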
